A study of Solanum pimpinellifolium with 6 samples.

How the data were processed

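RNA of 6 libraries was measured by RNA sequencing, 3 labelled RNAi line 207 and 3 labelled nontransgenic sibling, all from fruits 2 days post anthesis by their sample labels. Groups and replicate numbers were taken from the labels. The series design calls the libraries biological replicates. A stranded mRNA library kit is named in the labels' protocols.

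The authors deposited 1 table with a value per gene and library, read here as FPKM because the values are not whole numbers and do not sum to a constant, and because TopHat 1.3.2 and Cufflinks are named per the submitters' processing notes. The unit itself, the genome build, the annotation release and the scaling between libraries are not given in the sources used here. The same table holds the authors' own p-value and q-value for each gene, with 1 where a gene was not tested. Of its 34727 rows, 4 held no values and were left out. The deposited column of log2 fold changes was not used. FPKM values estimated by likelihood can share reads between overlapping or near-identical genes, so members of gene families such as the chlorophyll a-b binding genes and the defensins are less certain than single-copy genes.

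Depth per library is unknown. Whole reads could not be recovered, since gene lengths were not used and the values are model estimates. The worth of 1 read relative to sibling replicate 1 was taken as the most frequent ratio between low values (0.2 to 3 FPKM in that library) and gave relative depths from 0.384 to 1. Low values in the shallower libraries are the least precise.

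Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an empirical Bayes prior that follows the mean level, on the 15766 genes with a value of at least 1 in 3 or more libraries. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Folds in linear terms are ratios of group means. No linear fold or mean is given for a group at 0 or near 0. A log2 fold change of such a gene depends on the 1 added before the logarithm. On simulated data for this comparison with 50 changed genes per fold size among 15766, the test called 22 genes changed 8-fold, 11 changed 4-fold, 2 changed 2-fold and 0 changed 1.5-fold, with 2 false calls among 37. Most simulated changes were missed at every fold size, 8-fold included. The simulation gave far fewer calls than the 1585 in the data, and the adjustment is stricter where few genes change. Its share of missed changes therefore does not carry over to the real comparison.

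Before the data were examined, 24 gene lists were fixed, 12 by gene identifier and 12 by words in the deposited gene description: the RNAi target, ABA biosynthesis, carotenoid biosynthesis, ABA catabolism, ABA signalling, ripening, ethylene, gibberellin and auxin in fruit set, floral organ MADS box, shoot meristem, pollen, fruit size and shape, cell division, ribosomal proteins, photosynthesis, cell wall remodelling, defence, heat shock and dehydration, auxin response, seed storage, pollen and anther, C2H2 zinc finger, flavonoid and phenylpropanoid, and lipid transfer and cuticle. The single gene of the pollen list, LAT52, and the target have no set test. For the other 22 lists, limma's camera was run with a preset correlation of 0.01 and again with an estimated correlation, one-sided Fisher's exact tests were run in each direction (44 tests), and list medians were set against 10000 random lists matched on mean level. No set call held at an adjusted p of 0.05 with the estimated correlation. That version also draws on the few residual degrees of freedom of 6 libraries, which raises p by itself. For the ethylene list the estimated correlation was 0.005, below the preset 0.01, yet the camera p went from 1e-05 to 0.0103. A set call lost with that version therefore does not by itself show correlation between genes. Some lists share genes, such as the cell wall and the pollen and anther lists with 10 in common.

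The genes named were set by a rule fixed beforehand: the target, all genes of ABA synthesis and catabolism, in each other list up to 4 members with the smallest p and every called member of the ripening, ethylene and fruit set lists, the 10 genes with the largest fold in each direction among non-overlapping groups with means of at least 1, and up to 3 genes per direction at 0 in a group. Not all of them are described. Gene symbols such as SlZFP2 and NCED1 were paired with identifiers from memory of the literature and not from the table, which gives identifiers and descriptions only. The reference gene table supplied (S. pimpinellifolium LA1246 assembly) matched 0 of the identifiers, so no coordinates are given.

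Alternatives tried were other thresholds, filters, pseudocounts and scalings, the authors' deposited p-values, the replicate number as a block, and each library left out in turn.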

Results

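RNA from tomato fruits collected 2 days post anthesis (dpa) from hand-pollinated flowers was profiled by RNA sequencing. The plants were the wild currant tomato Solanum pimpinellifolium, accession LA1589. By the labels, 3 libraries came from RNAi line 207, in which the zinc finger transcription factor SlZFP2 was the silencing target, and 3 came from its nontransgenic sibling. The series design describes line 207 as defective in fruit set and in the synthesis of abscisic acid (ABA), a stress and dormancy hormone, and gives no direction for the latter. The comparison asks which transcripts differ between young fruits of the 2 genotypes. One protocol label names shoot tips as the tissue extracted, whereas the sample labels name fruits. The tissue is given here as fruits on the sample labels alone. The deposited values were read as FPKM (fragments scaled by gene length and library depth). They cover 34723 genes, of which 12373 were at 0 in all 6 libraries and 15766 had a value of at least 1 in 3 or more libraries. Read totals were not used, and only a relative depth could be derived from the steps between low values. Taking sibling replicate 1 as 1, it was 0.801 and 0.863 in sibling replicates 2 and 3 and 0.384, 0.496 and 0.781 in line 207 replicates 1 to 3. The libraries labelled line 207 were the shallower ones.

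The RNAi target was read first, as a check of the labels. SlZFP2 (Solyc07g053570, described in the table as a zinc finger family protein) was at 10.3, 9.03 and 7.45 FPKM in the libraries labelled line 207 and at 2.89, 3.05 and 0.00147 FPKM in those labelled sibling. Every library labelled line 207 therefore lay above every library labelled sibling, against the direction that silencing of this gene would give. The log2 fold change was 1.97 ± 0.66 (SE) and did not pass the test over all genes (limma, Benjamini-Hochberg adjusted p = 0.112). Adjusted over its list of 1 gene, it passed as higher in limma, but not without line 207 replicate 1 (log2 fold change 1.88). The authors' deposited table gives a q of 1 for this gene, its mark for a gene not tested. For this reason the groups are called the libraries labelled line 207 and labelled sibling throughout, and each direction below is a direction between labels.

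The 2 groups of libraries were separated. The correlation of log2(FPKM + 1) values over the tested genes was 0.779 to 0.86 within groups and 0.694 to 0.755 between them. The first principal component, which held 39.6% of the variance, parted the labelled groups. The 3 libraries labelled line 207 were more scattered than the siblings, with a lowest correlation of 0.779 against 0.829. On the second component they ranged from -84.7 to 98.9, against -3.69 to 5.58 in the siblings.

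**Figure D1:**
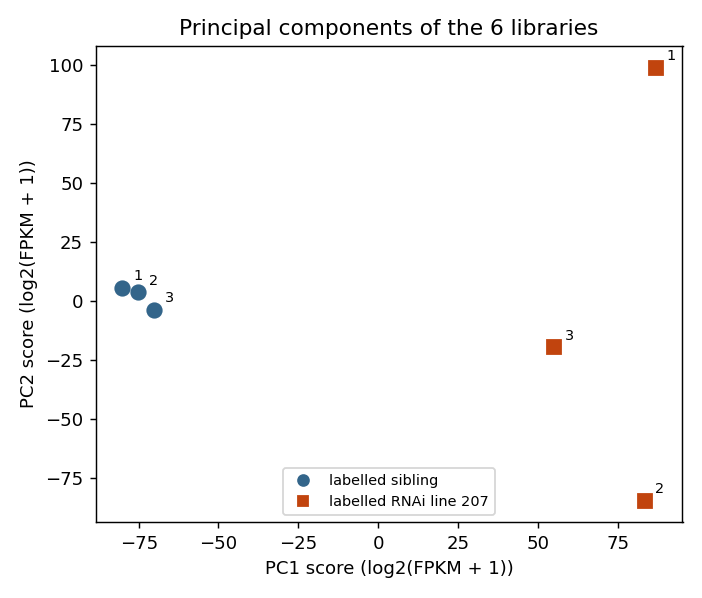
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1) over the 15766 tested genes, each point a library with its replicate number, circles for those labelled sibling and squares for those labelled RNAi line 207. The siblings lie together at PC1 scores of -80.1 to -70.2 and the labelled line 207 libraries at 55 to 86.9, with the target gene higher in the latter, against the label.

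Across the transcriptome, 790 genes were higher and 795 lower in the libraries labelled line 207, or 10.1% of those tested (limma, Benjamini-Hochberg adjusted p at most 0.05). Of these 1585 genes, 1398 differed by at least 1 on the log2(FPKM + 1) scale. The groups did not overlap for 5233 of the tested genes (33.2%), where chance gives 10%. NCED1 of ABA synthesis, 3 genes of gibberellin inactivation and ACO1 of ethylene synthesis were among those higher in labelled line 207, while the called genes of photosynthesis, ribosomal proteins, DNA replication and lipid transfer were mostly lower. The authors' deposited table calls 2722 genes at a q of at most 0.05, 1226 with a higher and 1496 with a lower mean in labelled line 207. It shares 1208 calls with limma. Of the limma calls, 161 were not tested in that table. Both directions come from the same values per library, and the groups did not overlap for any of the 1585 limma calls. Their match in direction was therefore fixed in advance. The number of limma calls fell whichever library was left out, and each such fit also has fewer samples. It was 1219, 706 and 949 without sibling replicates 1, 2 and 3. Without line 207 replicates 1, 2 and 3 it was 787, 711 and 815. Fewer samples and dependence on a particular library cannot be told apart from these counts. The same holds for the calls of single genes and lists lost below.

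ABA genes were led by NCED1 (Solyc07g056570, the NOTABILIS locus), whose product cleaves 9-cis-epoxycarotenoids in the rate-limiting step of ABA synthesis. Its level was 130 ± 44.5 FPKM (SD, n = 3) in the libraries labelled line 207 and 8.28 ± 2.81 (SD, n = 3) in the labelled siblings, a 15.7-fold difference of means (log2 fold change 3.81 ± 0.33 (SE), limma adjusted p = 0.00226). The authors' deposited q for NCED1 is 0.0785. Of the 8 tested genes of ABA synthesis, NCED1 was the 1 that passed over all genes. When adjusted over the list alone, 3 were higher and 1 lower. NCED2 (Solyc08g016720) averaged 17.1 ± 4.2 FPKM (SD, n = 3) against 6.01 ± 2.12 (limma adjusted p = 0.0747). Zeaxanthin epoxidase (Solyc02g090890), which acts upstream, averaged 28.1 ± 3.87 against 47.8 ± 6.18 (adjusted p = 0.0639). The authors' deposited q passes for both, at 0.00472 for NCED2 and 0.00152 for zeaxanthin epoxidase. The aldehyde oxidase AO1 (Solyc11g071620) was at 1.42, 3.92 and 4.12 FPKM in labelled line 207 and at 0.088 or less in each labelled sibling (adjusted p = 0.059). SITIENS (Solyc01g009230), of the last step, had values from near 0 to 6.28 FPKM. FLACCA (Solyc07g066480), described as a molybdenum cofactor sulfurase, had values from near 0 to 3.47 FPKM. Both differed by less than the spread between replicates (limma adjusted p = 0.71 and 0.72). The same held for Solyc12g041880 (adjusted p = 0.933). The violaxanthin de-epoxidase (Solyc04g050930) averaged 15.9 ± 3.98 against 20.6 ± 1.82 FPKM and did not pass (adjusted p = 0.452). As a set, the list did not pass (camera adjusted p = 0.249).

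Genes of ABA breakdown and response were also higher by label in part. Of the 3 tested ABA 8'-hydroxylase genes, CYP707A2 (Solyc08g005610) was at 8.02 ± 1.67 FPKM (SD, n = 3) in labelled line 207 and at 1.42 ± 0.411 in the labelled siblings (log2 fold change 1.89 ± 0.46 (SE), limma adjusted p = 0.0463). CYP707A1 (Solyc04g078900) averaged 22.7 ± 5.02 against 9.67 ± 5.76 FPKM (adjusted p = 0.113). Adjusted over the list alone, 2 members passed, both higher. CYP707A4 (Solyc01g108210) was at 3.27, 6.38 and 0 FPKM in labelled line 207 and at 1.24, 1.55 and 1.44 in the labelled siblings (adjusted p = 0.796). CYP707A3 (Solyc04g071150) stayed at 0.0346 FPKM or below and was not tested. Among 19 tested genes of ABA signalling, 2 were higher and 1 lower, both over all genes and adjusted over the list alone. The type 2C protein phosphatase Solyc05g052980 rose 4.06-fold, from 38.6 ± 13 to 157 ± 22.7 FPKM (SD, n = 3; limma adjusted p = 0.00856). Solyc03g096670 rose 3.54-fold (adjusted p = 0.0197). The lower gene was another type 2C phosphatase (Solyc08g062640), at 3.34, 8.71 and 6.09 FPKM in the labelled siblings and near 0 in labelled line 207 (adjusted p = 0.0208). It lost its call without sibling replicates 2 or 3 or any 1 line 207 library (adjusted p up to 0.0735). The number called was 1 without sibling replicate 3 or line 207 replicates 2 or 3. The transcription factor AREB1 (Solyc04g078840) averaged 25.3 ± 8.66 against 9.39 ± 2.91 FPKM (adjusted p = 0.0809). The CYP707A2 call was lost whichever library was left out (adjusted p up to 0.123). That of Solyc03g096670 was lost without sibling replicates 1 or 3 or line 207 replicates 2 or 3 (adjusted p up to 0.0727). Among the 11 tested genes of carotenoid synthesis, the source of ABA precursors, the beta-carotene hydroxylase gene BCH2 (Solyc03g007960) was higher, at 55.4 ± 4.02 against 9.09 ± 5.46 FPKM (SD, n = 3; adjusted p = 0.0189). It lost its call without any 1 of the 3 line 207 libraries (adjusted p up to 0.0703). PSY2 (Solyc02g081330, phytoene synthase) was lower, at 0.0117 FPKM or less in labelled line 207 against 22.9, 5.17 and 24.8 (adjusted p = 0.0156), a call lost without sibling replicate 3 or line 207 replicates 2 or 3 (adjusted p up to 0.0534). Adjusted over the list alone, 2 carotenoid genes were higher and 1 lower. In the authors' table CYP707A2 and Solyc08g062640 were not tested and carry a q of 1. The authors' deposited q is 0.134 for PSY2. It passes for CYP707A1 (0.00416) and AREB1 (0.0178), which limma did not call.

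**Figure D2:**
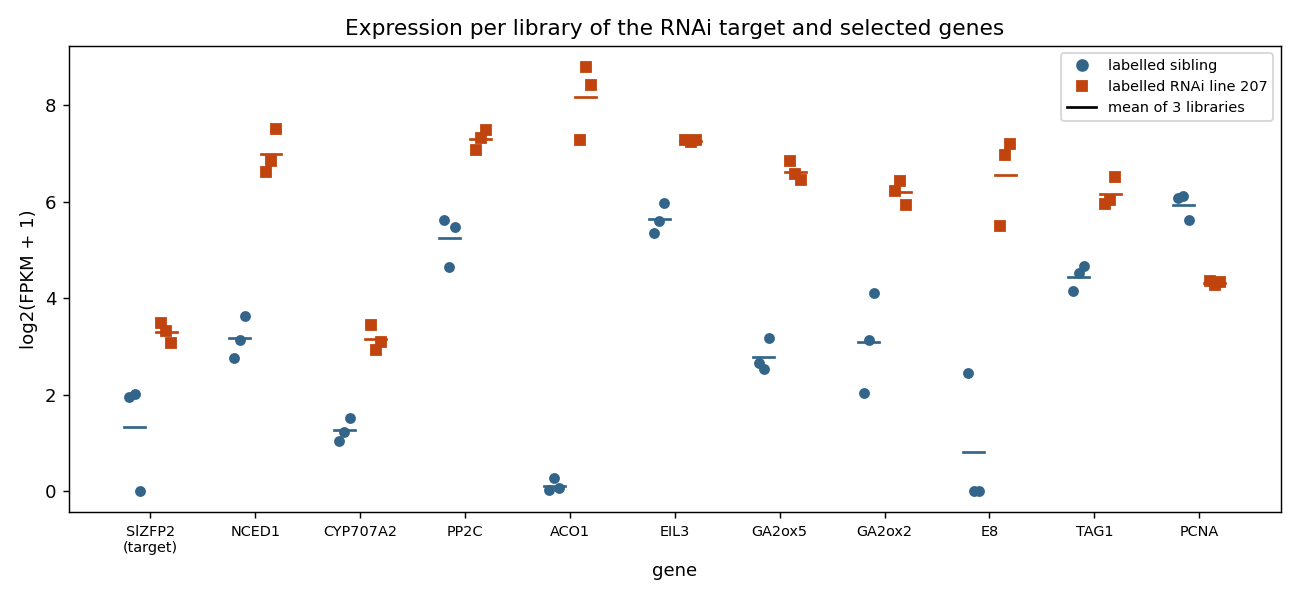
Expression of the RNAi target and 10 other genes on the log2(FPKM + 1) scale, each point 1 library (circles labelled sibling, squares labelled RNAi line 207) and each bar the mean of 3 libraries. NCED1, ACO1, GA2ox5 and E8 lie higher and PCNA lower in the libraries labelled line 207, and the target itself lies higher there, at 7.45 to 10.3 FPKM, against the label.

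Gibberellin promotes fruit set, and 3 genes for gibberellin 2-oxidases, which inactivate it, were higher in the libraries labelled line 207. GA2ox5 (Solyc07g061730) averaged 98.1 ± 14.4 FPKM against 6.03 ± 1.73 in the labelled siblings (SD, n = 3), a 16.3-fold difference (log2 fold change 3.84 ± 0.26 (SE), limma adjusted p = 0.000983). GA2ox2 (Solyc07g056670) was 8.08-fold higher, at 73.0 ± 12.6 against 9.03 ± 6.62 FPKM (adjusted p = 0.0136), and 13.4-fold without sibling replicate 3. GA2ox4 (Solyc07g061720) was 3.77-fold higher, at 110 ± 12.2 against 29.1 ± 18.9 (adjusted p = 0.0341), and 5.8-fold without sibling replicate 3. The auxin transporter gene PIN4 (Solyc05g008060) averaged 27.3 ± 5.89 against 14.6 ± 2.57 FPKM and did not pass (adjusted p = 0.106), while the authors' deposited q for it is 0.0128. These 3 oxidases were the only members of the 15 tested genes of gibberellin and auxin in fruit set to pass, over all genes and adjusted over the list alone. The list as a set did not pass (camera adjusted p = 0.249). GA2ox2 lost its call without sibling replicate 2 or line 207 replicates 1 or 2 (adjusted p up to 0.0594), and GA2ox4 without sibling replicate 2 or any 1 of the line 207 libraries (adjusted p up to 0.101). In the wider list of 78 auxin response genes 9 were higher and 4 lower, or 12 and 4 adjusted over the list alone, and the set did not pass (camera adjusted p = 0.172). The number called was 8, 7, 6, 5 and 6 without sibling replicates 2 and 3 and line 207 replicates 1, 2 and 3. The gene described as auxin response factor 1 (Solyc10g083210) rose 5.37-fold, from 6.27 ± 0.865 to 33.7 ± 1.75 FPKM (SD, n = 3; adjusted p = 0.00533). The small auxin-induced genes moved both ways. Solyc06g053290 rose 6.67-fold (adjusted p = 0.00917). Solyc01g110580 was at 10.6, 14.4 and 10.1 FPKM in the labelled siblings and listed at 0 in all 3 libraries labelled line 207 (adjusted p = 0.00632).

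Several ethylene and ripening genes were higher in labelled line 207 at this early stage. ACO1 (Solyc07g049530), an oxidase that makes ethylene in its final step, was at 155, 441 and 341 FPKM against 0.012, 0.2 and 0.0447 in the labelled siblings (log2 fold change 8.05 ± 0.42 (SE), limma adjusted p = 0.000504). With every sibling value at 0.2 FPKM or less, the size of this log2 fold change depends on the 1 added before the logarithm. The authors' deposited q for ACO1 is 0.32. The transcription factor gene EIL3 (Solyc01g096810), of the ethylene response, rose 3.07-fold, from 49.8 ± 11.3 to 153 ± 2.17 FPKM (SD, n = 3; adjusted p = 0.00588). These were the 2 of 15 tested ethylene genes to pass, with 3 higher and none lower adjusted over the list alone. Neither ACS2 (Solyc01g095080), at 2.31, 7.17 and 5.65 against 0.443, 0.554 and 0.507 FPKM, nor the receptor gene ETR4 (Solyc06g053710), at 29.0, 12.5 and 7.45 against 2.49, 5.01 and 0.328 FPKM, passed (adjusted p = 0.07 and 0.0975). The list median was 1.16 on the log2 scale (camera adjusted p = 7.35e-05, but adjusted p = 0.227 with an estimated correlation). Of 12 tested ripening genes 3 were higher and 1 lower, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0313, adjusted p = 0.229 with an estimated correlation). The set call was lost without line 207 replicate 1 (adjusted p = 0.0621) or replicate 2 (adjusted p = 0.0753), and with only genes at a mean of at least 10 FPKM (adjusted p = 0.0674). E8 (Solyc09g089580), a ripening-induced oxidase-like gene, was at 43.9, 124 and 145 FPKM in labelled line 207 against 4.49 FPKM in 1 labelled sibling and near 0 in the others (adjusted p = 0.00833). The authors' deposited q for E8 is 0.118. AP2a (Solyc03g044300), a transcription factor that restrains ethylene production in ripening fruit, rose 4.21-fold, from 6.7 ± 0.824 to 28.2 ± 4.9 FPKM (SD, n = 3; adjusted p = 0.0103). The lipoxygenase gene LOXC (Solyc01g006540), of flavour volatile synthesis, fell from 66.5 ± 23.5 to 10.4 ± 3.84 FPKM (adjusted p = 0.0087). The homeobox gene HB1 (Solyc02g086930) rose 3.07-fold (adjusted p = 0.0207), a call kept without sibling replicate 3 but lost without each of the other 5 libraries (adjusted p up to 0.0737).

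Among the 7 tested floral organ MADS-box genes, TAG1 (Solyc02g071730), which specifies stamen and carpel identity, was the 1 that passed, both over all genes and adjusted over the list alone. It rose 3.42-fold by label, from 21.0 ± 3.92 to 71.9 ± 16.3 FPKM (SD, n = 3; limma adjusted p = 0.00877). TM5 (Solyc05g015750) averaged 201 ± 25.2 against 167 ± 12.6 FPKM (adjusted p = 0.345). The set passed with the preset correlation (camera adjusted p = 0.0379, adjusted p = 0.358 with an estimated correlation). It did not pass without sibling replicate 1 (adjusted p = 0.0685), sibling replicate 2 (adjusted p = 0.066) or line 207 replicate 2 (adjusted p = 0.0924). Nor did it pass with a group mean of at least 1 (adjusted p = 0.0726) or a mean of at least 10 FPKM (adjusted p = 0.0876). Of 4 tested genes of fruit size and shape, the cell number regulator FW2.2 (Solyc02g090730) was at 5.5, 2.31 and 2.18 FPKM in the labelled siblings and listed at 0 in labelled line 207 (adjusted p = 0.0496, lost whichever library was left out, up to 0.117). The authors' table did not test FW2.2 and gives it a q of 1. OVATE (Solyc02g085500) averaged 25.0 ± 4.97 against 13.8 ± 9.41 FPKM and did not pass (adjusted p = 0.241), while the authors' deposited q for it is 0.0293.

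The called genes for photosynthesis were all lower in the libraries labelled line 207. Of 87 tested genes 45 were lower and none higher, and adjusted over the list alone 56 were lower and 1 higher (limma). The list median was -1.33 on the log2 scale (camera adjusted p = 3.76e-19, but adjusted p = 0.229 with an estimated correlation). Called genes were enriched in it (one-sided Fisher's exact test for lower genes, Benjamini-Hochberg adjusted p = 9.21e-34). The list was uneven. The 16 genes described as chlorophyll a-b binding protein had a median of -2.82, with 13 lower. The 10 whose description up to its first digit reads photosystem I P had a median of 0.0477, with 0 called. The chlorophyll a-b binding protein 4 gene (Solyc07g047850) averaged 161 ± 55.6 FPKM against 1717 ± 190 in the labelled siblings (SD, n = 3), which is 10.7-fold lower (adjusted p = 0.00226). A second antenna gene, Solyc12g011450, was 10.3-fold lower, at 45.0 ± 15.6 against 462 ± 14.9 FPKM (adjusted p = 0.00123). The photosystem I subunit gene Solyc08g013670 was 5.4-fold lower, at 79.2 ± 7.77 against 427 ± 10.3 FPKM (adjusted p = 0.000797). The number of photosynthesis genes called was 29 without line 207 replicate 2, its lowest value when a library was left out.

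The called genes of protein synthesis and DNA replication were mostly lower by label too. Of 344 tested ribosomal protein genes 44 were lower and none higher, or 107 lower and 2 higher adjusted over the list alone. The median was -0.60 on the log2 scale (camera adjusted p = 3e-13, adjusted p = 0.256 with an estimated correlation; Fisher's exact test for lower genes, adjusted p = 2.71e-07). They included the gene for chloroplast ribosomal protein S31 (Solyc05g052710), at 106 ± 7.28 against 229 ± 25.9 FPKM (SD, n = 3; limma adjusted p = 0.00828). Another was the cytosolic L13a-like gene (Solyc05g053670), at 217 ± 22.5 against 448 ± 12 FPKM (adjusted p = 0.0093). Of 145 genes with words for cyclins, DNA replication, histones or kinesins in their description 17 were lower and 2 higher, or 22 and 2 adjusted over the list alone. These words also match descriptions such as cyclin-dependent, so the list is wider than those classes. The median was -0.55 (camera adjusted p = 0.000231, adjusted p = 0.437 with an estimated correlation; Fisher's exact test for lower genes, adjusted p = 0.00748). The gene for proliferating cell nuclear antigen, the sliding clamp of DNA polymerase (Solyc06g076660), was 3.21-fold lower, at 19.0 ± 0.521 against 61.1 ± 11.2 FPKM (SD, n = 3; adjusted p = 0.0069). A DNA replication licensing factor (Solyc01g079500) was 4.11-fold lower (adjusted p = 0.00962) and a histone H2B gene (Solyc06g075800) 2.35-fold lower (adjusted p = 0.0108). An H1 histone-like gene (Solyc02g084240) went the other way, from 75.5 ± 24.6 to 420 ± 67.4 FPKM (adjusted p = 0.00465). The ribosomal count was 11, 21, 16, 28 and 16, and the replication count 12, 10, 9, 8 and 9, without sibling replicates 2 and 3 and line 207 replicates 1, 2 and 3, in that order. Without sibling replicate 1 the replication count was 12.

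Lipid transfer, cuticle and cell wall genes differed in both directions by label. Of 115 tested lipid transfer and cuticle genes 22 were lower and 1 higher, or 33 and 4 adjusted over the list alone. The median was -0.73 on the log2 scale (camera adjusted p = 0.000344, adjusted p = 0.229 with an estimated correlation; Fisher's exact test for lower genes, adjusted p = 8.26e-07). The lipid transfer protein gene Solyc08g067530 was 3.2-fold lower, at 164 ± 10 against 525 ± 62.6 FPKM (SD, n = 3; limma adjusted p = 0.00314). Solyc10g076200 rose 13.6-fold, from 52.9 ± 9.86 to 718 ± 174 FPKM (adjusted p = 0.000983). Among 166 cell wall genes 13 were higher and 22 lower, or 16 and 35 adjusted over the list alone. The set did not pass (camera adjusted p = 0.0512), though lower genes were enriched (one-sided Fisher's exact test, adjusted p = 0.000348). The pectinesterase gene Solyc01g091050 rose 17.0-fold, from 16.0 ± 4.23 to 273 ± 45.3 FPKM (SD, n = 3; adjusted p = 0.000797). The xyloglucan endotransglucosylase gene Solyc01g099630, whose product restructures walls, was 9.39-fold lower, at 18.2 ± 2.64 against 171 ± 33.5 FPKM (adjusted p = 0.000983). The list also holds an invertase inhibitor (Solyc12g099200) by its description, which rose 6.77-fold (adjusted p = 0.000983). The lipid transfer count was lowest without sibling replicate 2, at 7, and was 13, 10 and 10 without sibling replicate 3 and line 207 replicates 1 and 2. The cell wall count was lowest without line 207 replicate 2, at 16, and was 18, 20, 19 and 22 without sibling replicates 2 and 3 and line 207 replicates 1 and 3.

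Defence and stress genes were split. Of 233 tested defence and wound genes 24 were higher and 19 lower, or 32 and 22 adjusted over the list alone. Higher genes were enriched (one-sided Fisher's exact test, adjusted p = 0.00584), though the set did not pass (camera adjusted p = 0.172). Proteinase inhibitor I (Solyc09g089540) averaged 2370 ± 764 FPKM in labelled line 207 against 84.6 ± 36 (SD, n = 3), a 28.0-fold difference (limma adjusted p = 0.00136). The chitinase gene Solyc07g009500 was at 202, 336 and 366 FPKM in the labelled siblings and listed at 0 in all 3 libraries labelled line 207 (adjusted p = 0.000239). An ethylene response factor (Solyc01g090340), which the description places in this list, was 6.38-fold lower (adjusted p = 0.00289). Among 153 heat shock and dehydration genes 10 were higher and 8 lower, or 10 and 10 adjusted over the list alone. The dehydrin gene Solyc04g082200 rose 6.75-fold, from 72.3 ± 24.5 to 488 ± 64.7 FPKM (SD, n = 3; adjusted p = 0.00312). The phenylpropanoid list had 5 higher and 4 lower of 38, or 5 and 5 adjusted over the list alone. One was a phenylalanine ammonia-lyase gene (Solyc09g007920) that rose 2.79-fold (adjusted p = 0.00728). Another, Solyc10g086180, was 2.76-fold lower, at 77.0 ± 19.5 against 213 ± 63.7 FPKM (SD, n = 3; adjusted p = 0.0268). Its call was lost without sibling replicates 2 or 3 or line 207 replicates 1 or 2 (adjusted p up to 0.0939). Of 77 C2H2 and related zinc finger genes 5 were higher and 1 lower, or 3 and 0 adjusted over the list alone. Solyc01g107170 was at 123 ± 39.4 against 8.08 ± 0.649 FPKM (SD, n = 3; adjusted p = 0.00168). The defence count fell to 22, 23, 22 and 28, and the heat shock count to 10, 9, 11 and 8, without sibling replicate 2 and line 207 replicates 1, 2 and 3. Without sibling replicates 2 and 3 and line 207 replicates 1, 2 and 3, the phenylpropanoid count was 2, 2, 3, 1 and 2 and the zinc finger count 2, 3, 2, 1 and 1.

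Lists named for other tissues were also read. Of 51 tested genes with pollen or anther terms in their description 4 were higher and 6 lower, or 5 and 9 adjusted over the list alone (camera adjusted p = 0.0806). Several matched by a protein domain name alone and mark no tissue. Those that moved included the expansin gene Solyc02g088100, 5.2-fold lower in labelled line 207 (limma adjusted p = 0.0062), and a pistil extensin-like gene (Solyc02g078100), 37.7-fold higher (adjusted p = 0.00451) and 78.3-fold without sibling replicate 3. The number called was 6 without sibling replicate 2 or line 207 replicates 2 or 3. The pollen gene LAT52 (Solyc10g007270) was at 6.71, 7.87 and 8.24 FPKM against 7.58, 37.2 and 39.4 and did not pass over all genes (adjusted p = 0.189). Without sibling replicate 1 it was called lower (adjusted p = 0.0137). Adjusted over its list of 1 gene, it passed as lower, but not without any 1 of the other 5 libraries (log2 fold change -1.52 to -1.08). Both tested shoot meristem genes, TKN1 (Solyc04g077210) at 5.12 ± 2.29 against 13.1 ± 7.48 FPKM (SD, n = 3) and TKN2 (Solyc02g081120) at 7.72e-05 to 5.84 FPKM, did not pass (adjusted p = 0.329 and 0.633). The authors' deposited q is 0.00964 for TKN1. Of 13 seed storage and embryo genes 2 were higher and none lower, or 4 and 0 adjusted over the list alone. The oleosin gene Solyc06g060840 was at 11.7, 18.1 and 11.9 FPKM in labelled line 207 and listed at 0 in the labelled siblings (adjusted p = 0.00588). The number called was 1 without sibling replicates 1 or 2 or line 207 replicates 1 or 2.

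**Figure D3:**
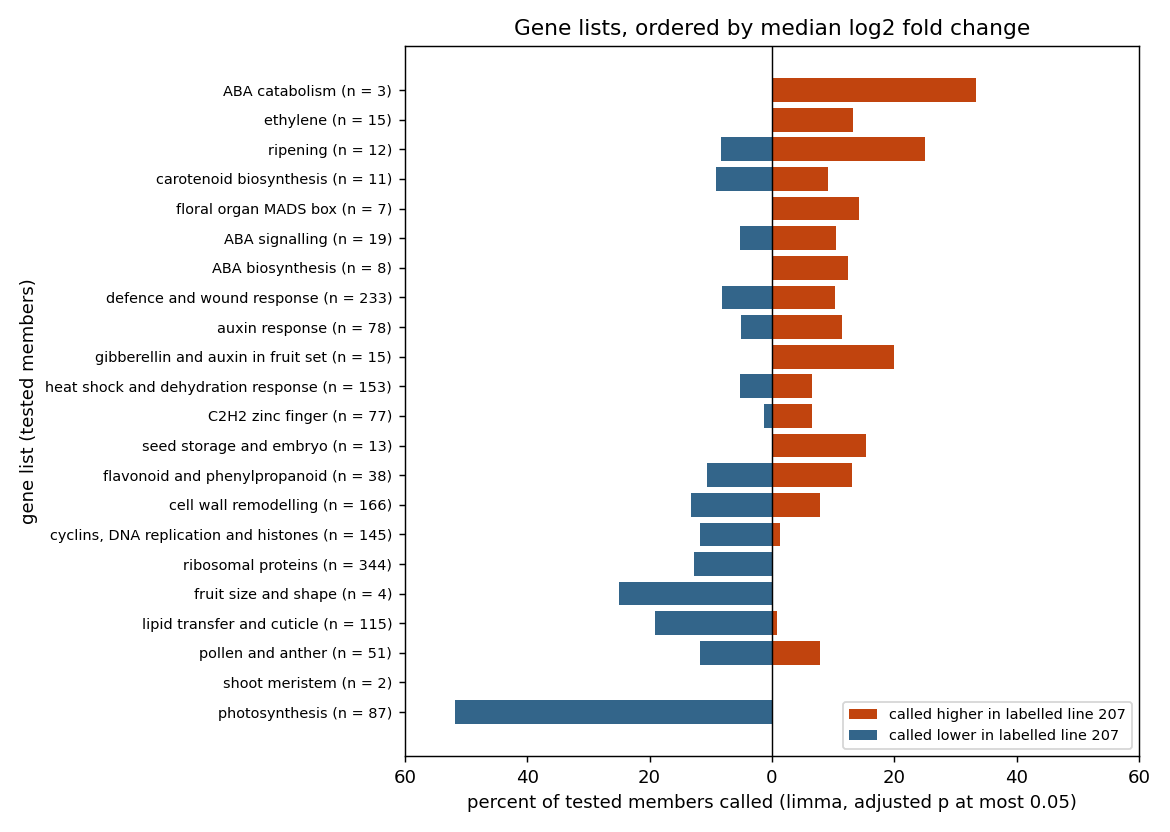
Percent of the tested members of 22 gene lists called higher (to the right) or lower (to the left) in the libraries labelled RNAi line 207 (limma, adjusted p at most 0.05), with the number tested and lists ordered by median log2 fold change. Photosynthesis shows the longest bar, with 45 of 87 members lower. The target gene itself is higher in labelled line 207, against the label.

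The genes with the largest folds by label included proteinases, an amide synthase and defensins. A cathepsin B-like cysteine proteinase gene (Solyc02g076910) averaged 355 ± 93 FPKM in labelled line 207 against 2.86 ± 1.64 (SD, n = 3), a 124-fold difference (limma adjusted p = 0.000504). Another gene described as cathepsin B (Solyc02g069110) was at 158, 93.3 and 101 FPKM in the labelled siblings and listed at 0 in labelled line 207 (adjusted p = 0.000504). Asparagine synthase (Solyc06g007180), which makes the main nitrogen transport amide, was at 436, 482 and 582 FPKM against 6.51, 44.3 and 0.00155 (adjusted p = 0.0248). That call was lost without sibling replicate 1 or any 1 of the line 207 libraries (adjusted p up to 0.0794). A carbonic anhydrase gene (Solyc02g067750) was 64.7-fold higher, at 171 ± 34.0 against 2.65 ± 2.56 FPKM (adjusted p = 0.00251), and 141-fold without sibling replicate 3. The authors' deposited q is 0.0545 for asparagine synthase and 0.0812 for the carbonic anhydrase. The defensin genes Solyc07g007710 and Solyc07g007730 were at 347, 654 and 132 and at 172, 256 and 117 FPKM in labelled line 207 and listed at 0 in every labelled sibling (adjusted p = 0.000983 and 0.000504). On the lower side, Solyc08g079100 carries the description CRABS CLAW, the name of a carpel and nectary regulator. Whether this locus has that role was not checked. It was at 103, 84.1 and 87.3 FPKM in the labelled siblings. In labelled line 207 it was at 10.5 in 1 library and near 0 in the others (limma adjusted p = 0.0165). The call was kept without line 207 replicate 2 and lost without each of the other 5 libraries (adjusted p up to 0.0635). The authors' deposited q for it is 0.192. Of all genes called, 49 of the higher ones were listed at 0 in every labelled sibling and 77 of the lower ones at 0 in every library labelled line 207. Such a 0 can be a failed estimate, since 2209 genes were near 0 in 1 library and at 10 FPKM or more in another of the same group.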

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

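The scalings by median ratio and by quantiles, the filter on a mean of at least 10 FPKM, the removal of genes near 0 in a library and the fit without an intensity trend were chosen after seeing the data. The number of genes called was 1585 and stayed between 1167 and 2045 with a minimum fold, a filter on group means, a pseudocount of 0.1 or those 5 choices. It fell to 410 at an adjusted p of 0.01 and to 496 without a filter on low values (34723 genes tested), and rose to 2723 at 0.10. The authors' deposited values gave 2722, as did Benjamini-Hochberg adjustment of their p-values over tested genes, with or without a minimum group mean of 1. With each library left out in turn, the number called was 706 to 1219. Fewer samples and dependence on a library cannot be told apart there. With the replicate block, limma called 894 genes (486 higher and 408 lower). Libraries with the same number did not deviate together (correlations of 0.015, -0.023 and -0.022 over 8713 genes), so the numbers do not pair them. The share of higher genes among those called was 49.8%. It was 52.4% at 0.01, 54.4% with the replicate block, 52.7% with median-ratio scaling, 54.2% with quantile normalization, 45.0% in the authors' values and 43.6% to 60.1% with a library left out; the cause was not tested. The log2 fold change of SlZFP2 stayed positive, from 1.31 to 3.18. It did not pass over all genes under any limma alternative run on it (adjusted p 0.0728 to 0.348). The filter on a mean of at least 10 FPKM removed this gene, so that alternative gives no value for it. For 113 named genes, 1872 of 2114 values under the alternatives kept direction and call, 217 lost the call, 18 gained it and 7 changed sign. The last were all of uncalled genes. CYP707A4 was at -0.22 with a pseudocount of 0.1 and at -0.22 to 1.22 with a library left out. Solyc12g041880 was at 0.0372 when centred on the median, and at -0.241 to 0.0838 with a library left out, including 0.0238 without line 207 replicate 2. TKN2 was at -1.29 to 0.0201 and SITIENS at -0.0773 to 1.34 with a library left out. NCED1, GA2ox5 and ACO1 were called under every limma alternative run on them; the authors' deposited q is 0.0785 for NCED1 and 0.32 for ACO1. Centring subtracted -0.0817, the median log2 fold change of genes with a mean of at least 1 in both groups. Without a filter on low values the list medians shrank to 0 for lipid transfer, -0.09 for cell division, -0.30 for ribosomal proteins and -0.69 for photosynthesis, with genes at 0 throughout counted in. Taking 1 feature per gene changes nothing here, and a count model was not run for lack of counts. Relative depth limits the line 207 libraries most.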

Other observations

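Gene families were read from the words of the gene descriptions, with directions again drawn from labels that the target gene goes against. Some repeat genes of the fixed lists, such as GA2ox genes under gibberellin and CYP707A genes under cytochrome P450. Of 16 tested genes described as gibberellin oxidases or other gibberellin proteins 6 were higher and none lower (one-sided Fisher's exact test over 283 description phrases, Benjamini-Hochberg adjusted p = 0.0114), and of 135 described as cytochrome P450 18 were higher and 13 lower (adjusted p = 0.0157 for higher). Of 8 genes whose description starts with glyceraldehyde, the dehydrogenases of glycolysis and carbon fixation, 5 were lower and none higher (adjusted p = 0.003). Of 26 genes with the NAC domain description 6 were higher and 1 lower, which did not pass (adjusted p = 0.0629). These tests were chosen after seeing the data.

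The explanations below were tested on the same data. The tests of the target gene, of depth and of dominant genes were chosen after the result was seen, and the bounds of the others were set before it. The split of the libraries into the labelled groups called 1585 genes, and the highest of the other 9 of the 10 possible splits called 1. It was the 1 split with so many, but 10 splits are too few for a share under 0.05.

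The first pattern is the RNAi target, SlZFP2, which was higher in every library labelled line 207. A single mislabelled library is argued against, since the lowest correlation within a group (0.779) was above the highest between groups (0.755). An exchange of labels between the 2 groups could give the log2 difference of 1.97, and so could reads from the silencing transgene that map to the target, where the lowest labelled line 207 value was 2.44 times the highest sibling value. These cannot be told apart with values per gene, because neither the position of the reads in the gene nor a marker independent of the labels was used here. The series design names a defect in fruit set, and higher GA2ox and lower PCNA levels in labelled line 207 would go with it, but no level of these genes is known for either genotype apart from the labels. For ABA synthesis it gives no direction to set NCED1 against. A true rise of the endogenous transcript in young fruit stays open as well, untested.

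The second pattern is the 2209 genes near 0 in 1 library and at 10 FPKM or more in another of the same group. Loss of whole regions is argued against, since the next gene in identifier order was near 0 in the same library 1.34 times as often as genes in general, where 3 times was the bound set for it. A move of reads to the next gene in identifier order is argued against too, since 50.9% of these were higher in the low library. The preceding gene and related genes elsewhere were not checked, so a move of reads to those stays open. Sampling of few reads may account for part: such genes made up 20.5% of genes with a group maximum of 10 to 20 FPKM and 3.4% of those at 100 or more, a ratio of 0.166 that lies between the bounds set for and against it. Whether sampling or failed estimates left these values cannot be told apart while gene lengths and reads are unknown, and 18 of these genes were called.

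The third pattern is the lower median of the photosynthesis, ribosomal protein, cell division and lipid transfer lists in the libraries labelled line 207. Of their members 42 of 87, 300 of 344, 126 of 145 and 92 of 115 were not called. No set call held with an estimated correlation (camera adjusted p 0.229 to 0.437), a test that is weak with 6 libraries. Lower depth is argued against as the whole cause, since over members with a mean of at least 50 FPKM the highest of the 4 medians was still -0.476. So are a few dominant genes, which would lower all others alike: the 15075 tested genes outside these lists had a median of -0.0622 (-0.0738 to -0.0398 with a library left out). The 3 genes with the highest values summed over all libraries took less of the summed FPKM in labelled line 207 (5.38% to 16.1%) than in the siblings (17.5% to 29.9%). Nor did the 3 highest genes of any labelled line 207 library, taken per library, have a larger share than those of any sibling. A hypothesis is that these fruits may have been in a state like growth arrest or senescence. Genes described with senescence or autophagy, a list written before its values were seen, had a median of 0.429, at the 99.97th percentile of 10000 random lists, with 8 of 49 higher and 1 lower. Its parts differed. The 13 genes described as autophagy-related protein had a median of 0.565, with 3 higher. The 10 described as senescence-associated protein, with no further word or number, had a median of -0.516, with 1 higher and 1 lower. Among those described as senescence-associated protein-like, Solyc04g049080 and Solyc07g054160 were higher (limma adjusted p = 0.0331 and 0.0359). Solyc09g063070, of the same wording, was not called (adjusted p = 0.904). The 10 described as leaf senescence protein had a median of -0.0412, with 0 called. The stay-green genes Solyc12g056480 (53.8, 71.4 and 89.4 against 0, 1.83 and 5 FPKM, limma adjusted p = 0.00797) and Solyc08g080090 (adjusted p = 0.0119) and the autophagy gene Solyc07g064680 (adjusted p = 0.0239) were higher, but the set had a p of 0.125 with an estimated correlation (0.0108 with the preset one), and genotype, fruit stage and label remain confounded.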
